A study of Mus musculus with 40 samples.

How the data were processed

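The study measured H3K27ac and H3K4me1 by ChIPmentation in sorted haematopoietic stem and progenitor cells of 21-day-old mice of 6 genotypes. Of its 40 samples, 39 carried a mark and formed 12 groups by genotype and mark, 9 groups of 3 and 3 groups of 4 (NUP98-HOXD13 for H3K27ac, Flt3-ITD/NUP98-HOXD13 for both marks), and 1 was an input control, which was not analysed here. Groups were taken from the sample labels. The genotype label Runx1-het goes with source names that join Runxf and Vav, read here as a floxed Runx1 allele and a Vav-driven transgene, and the exact alleles are not given in the sources used here. Per the submitters' processing notes, reads were aligned with BWA to mouse genome build mm10 (GRCm38) and peaks were called with MACS2, with versions not given in the sources used here. The deposited peak lists number 12, 1 per group, pooled over the samples of the group, so no value per sample was used. The threshold applied to the peaks before deposit is not given in the sources used here, and the lists held 39.3 to 70.6% (H3K27ac) or 52.0 to 68.1% (H3K4me1) of the highest peak number in their names.

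Each deposited list gives, per peak, a score (an integer of at most 1000), a ratio, which is the authors' fold enrichment over control at the peak summit, the −log10 p and the −log10 q of the authors' peak caller, and the position of the summit (other). The deposited ratio, a fold enrichment, was used to rank, filter and describe peaks within a list and never subtracted between lists, and the deposited −log10 p values set the order of peaks where lists were shortened. Per the labels no read depth is stated, so depth and its precision are unknown, and no depth-based limit is given.

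For each mark the peaks of the 6 lists were merged (1 bp overlap) into union regions, and a list held a region if a peak of it overlapped the region by 1 bp. A region was gained if the mutant list held it and the reference list did not, and lost in the reverse case. The 7 comparisons were each of the 5 mutants against wild type, Flt3-ITD/NUP98-HOXD13 against NUP98-HOXD13, and Flt3-ITD/Runx1-het against Runx1-het. The last 2 share no list with Flt3-ITD against wild type. Shares are given with 95% Wilson intervals, which cover counting error only. The pooled lists give no value per sample, so groups were not tested against each other and no p-value was computed. Similarity of lists is the Jaccard index of their regions.

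Genes and transcription start sites came from GENCODE mouse release 21 (21827 protein-coding genes, 41433 distinct start sites). A region went to the gene with the nearest start site within 50 kb, and a promoter was the range within 1 kb of a start site. A gene counted as having a promoter peak in a list if a peak of that list lay within that range. For each of 15 gene lists (282 entries, of which 1 is not in the annotation), the gained share of the changed regions was ranked among 10000 random lists with the same number of union regions per gene (counted up to 15). A percentile of at most 2.5 or in the top 2.5 stood outside the central 95%. The lists were HSC and multipotent progenitor, HOX and cofactor, interferon response, STAT5 target, MAPK feedback, granulocyte, monocyte and macrophage, dendritic cell, B lymphoid, T and NK cell, erythroid, megakaryocyte, mast cell, basophil and eosinophil, genes not expressed in blood (negative control) and ubiquitous promoters (positive control).

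Named genes followed a rule fixed before the data were examined. Per comparison they are the genes of the 5 gained and 5 lost H3K27ac regions with the highest fold enrichment, up to 4 members per gene list with the most gained or lost regions, and the genes behind the genotypes (Flt3, Runx1, Nup98 and Hoxd13). Genes named by a promoter peak alone were chosen after the values were seen.

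The overlap of the Flt3-ITD effect between backgrounds, and the regions held by a double mutant alone, were set beside independence and beside a simulation in which each list holds a region with a probability given by the number of lists that hold it (1000 draws, 200 for equal-length lists). A second simulation (100 draws), which keeps the number of lists per region and draws which lists hold it, was added after the data were seen, as were the counts of regions that follow a genotype factor, the gene lists without 1 member (2000 random lists each) and random lists matched also on 5 groups of fold enrichment. Alternatives planned before were equal-length lists (the 31978 strongest H3K27ac and 72682 strongest H3K4me1 peaks per list by −log10 p), a threshold of −log10 q of at least 5, the strongest peaks of 1 list against the full other list, coverage of at least 0.5 of the union region, direct comparison of list pairs, autosomes only, start sites within 100 kb and promoters within 2 kb.

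The procedure was tested on simulated data. Of 2000 gains and 1500 losses planted in a copy of the wild-type H3K27ac list, 2000 and 1500 were recovered, and 14 of 14 counts equalled those of bedtools. Of 100 random lists of 18 genes without an effect, 5 fell outside the central 95%, and of 50 lists with 80% of changed regions gained, 42 lay above it. Simulated list lengths deviated from the real ones by at most 0.515%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used. Motifs in changed regions were planned and not analysed here, since the genome sequence was not at hand, and the signal tracks were not used here.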

Results

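H3K27ac, a histone mark of active promoters and enhancers, and H3K4me1, a mark of enhancers, were mapped by ChIPmentation in sorted mouse haematopoietic stem and progenitor cells at 21 days of age. ChIPmentation is chromatin immunoprecipitation in which the transposase Tn5 adds the sequencing adapters to chromatin held on the antibody beads. The 6 genotypes were wild type, Flt3-ITD (an internal tandem duplication that leaves the receptor kinase FLT3 active without ligand), NUP98-HOXD13 (a fusion of a nucleoporin with a homeodomain transcription factor), Runx1-het (the genotype label, read here as 1 altered copy of the transcription factor gene Runx1), and the double mutants Flt3-ITD/NUP98-HOXD13 and Flt3-ITD/Runx1-het. The 39 samples with a mark formed 12 groups, 9 of 3 samples and 3 of 4 samples. Each group gave 1 pooled peak list, so no value per animal was used, no p-value is given, and nothing measures the spread between animals. The 95% Wilson intervals cover counting error only. A region outside a list is one where no peak passed the authors' threshold, and read depth is unknown from these files.

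The H3K27ac lists held 43363 peaks in wild type, 36008 in Flt3-ITD, 36210 in NUP98-HOXD13, 31978 in Runx1-het, 33935 in Flt3-ITD/NUP98-HOXD13 and 42677 in Flt3-ITD/Runx1-het. The H3K4me1 lists held between 72682 peaks (Runx1-het) and 117039 peaks (Flt3-ITD/Runx1-het). The wild-type H3K27ac list had the most peaks but covered the least sequence, 28.0 Mb against 34.7 to 44.6 Mb, with a median peak width of 389 bp against 586 to 888 bp, and 9999 of its peaks lay in regions that no other list held. Merging the 6 lists gave 71518 H3K27ac regions, of which 13816 were in all 6 lists and 37612 in 1 list. For H3K4me1 the merged set had 181776 regions, 18127 in all 6 lists and 89663 in 1. The fold enrichment quoted below is the authors' own value for a peak and ranks peaks within a list.

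Promoter H3K27ac set the control lists apart in every genotype. All 12 ubiquitously expressed genes of the positive control list, among them Actb and Gapdh, had a promoter peak in each of the 6 lists, and at most 1 of the 18 genes of the list not expressed in blood had one. Promoter peaks stood at 2 or 3 of 17 T and NK cell genes, at 7 to 9 of 15 B lymphoid genes, at 5 to 9 of 14 megakaryocyte genes, at 5 to 8 of 17 erythroid genes and at 2 to 4 of 15 genes of the mast cell, basophil and eosinophil list. Monocyte and macrophage genes had promoter peaks at 6 to 8 of 17 members, dendritic cell genes at 4 to 7 of 15, and granulocyte genes at 4 (wild type) to 9 (Flt3-ITD/Runx1-het) of 18. Over all 21827 protein-coding genes, 8598 promoters had a peak in wild type and 8601 to 10074 in the mutants. At Flt3 the promoter fold enrichment ranged from 17.8 (Flt3-ITD/Runx1-het) to 38.4 (Flt3-ITD), at Runx1 from 7.23 (wild type) to 21.6 (Runx1-het), and at Nup98 from 23.1 to 37.4. No list had a promoter peak at Hoxd13, so the endogenous partner gene of the fusion carried no listed H3K27ac at its promoter.

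Flt3-ITD against wild type asks what the mutation does to the enhancer and promoter landscape on its own. The strongest gained H3K27ac region lay at the promoter of Socs2, a feedback inhibitor of cytokine signalling induced by STAT5 (chromosome 10, 95408369 to 95418536). It had a fold enrichment of 15.4 in Flt3-ITD, 12 in Flt3-ITD/NUP98-HOXD13, 17.8 in Flt3-ITD/Runx1-het and 3.75 in NUP98-HOXD13, and was outside the wild-type and Runx1-het lists. The other 4 of the 5 strongest gained regions, near Ect2l (14.7), Gatb (13.8), Hist1h2an (13) and Arl2bp (11.9), were in all 5 mutant lists and missing from wild type alone. Of the strongest lost regions, those near Tfcp2 (8.62 in wild type), Sh3gl1 (7.97) and Dop1b (7.64) were missing from the Flt3-ITD list alone, the region in Selp, which encodes P-selectin of platelets and endothelium, was in wild type alone (7.88), and the one near 1700016K19Rik (11.3) was outside all 3 Flt3-ITD lists.

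Among the gene lists, the STAT5 targets had the most one-sided gain in Flt3-ITD, with 31 H3K27ac regions gained and 11 lost, at percentile 99.7 of 10000 random gene lists with as many regions per gene. The cyclin gene Ccnd3 had 10 gained and 2 lost regions, Socs2 6 and 0, Socs1, another cytokine feedback inhibitor, 3 and 0, and the survival kinase gene Pim1 3 and 3. Without Ccnd3, the member whose removal moved it most, the percentile was 98.5. STAT5 target promoters with a peak numbered 12 of 18 in Flt3-ITD and 10 in wild type. The mast cell, basophil and eosinophil list had 13 regions gained and 5 lost (percentile 97.55), among them Kit, the stem cell factor receptor (4 and 1), and Gata2 (2 and 0). This fell to 70.7 in equal-length lists and to 93.7 without Gata2. A Gata2 promoter peak was in wild type and missing from Flt3-ITD, although no Gata2 region counted as lost. Interferon response genes had 28 gained and 16 lost regions (percentile 95.9), with Eif2ak2 and Ifit3 at 2 and 0 each, and monocyte and macrophage genes 14 and 28 (percentile 2.74, and 2.19 against random lists matched also on fold enrichment, outside the central 95%), with the coagulation factor gene F13a1 at 0 and 6. HSC and multipotent progenitor genes had 52 gained and 40 lost (percentile 76.0).

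Over the genome, Flt3-ITD gained 12278 H3K27ac regions (39.6% of its regions, interval 39.1 to 40.2%) and lost 13540 of the wild-type regions (42.0%, 41.4 to 42.5%), a gained share of 47.6%. With each list shortened to its 31978 strongest peaks, 11135 were gained and 6986 lost, a gained share of 61.4%, so the direction of the overall balance depended on list length. Changed regions were weak ones: gained regions had a median percentile of 25.6 within the Flt3-ITD list, where regions shared with wild type had 69.1. H3K4me1 regions gained numbered 40209 and lost 23499, against 27829 and 27438 in equal-length lists. STAT5 targets also stood apart for H3K4me1, with 118 regions gained and 26 lost (percentile 99.99), and T and NK cell genes had 36 and 8 (percentile 99.2) although their H3K27ac regions numbered 2 gained and 7 lost.

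**Figure D1:**
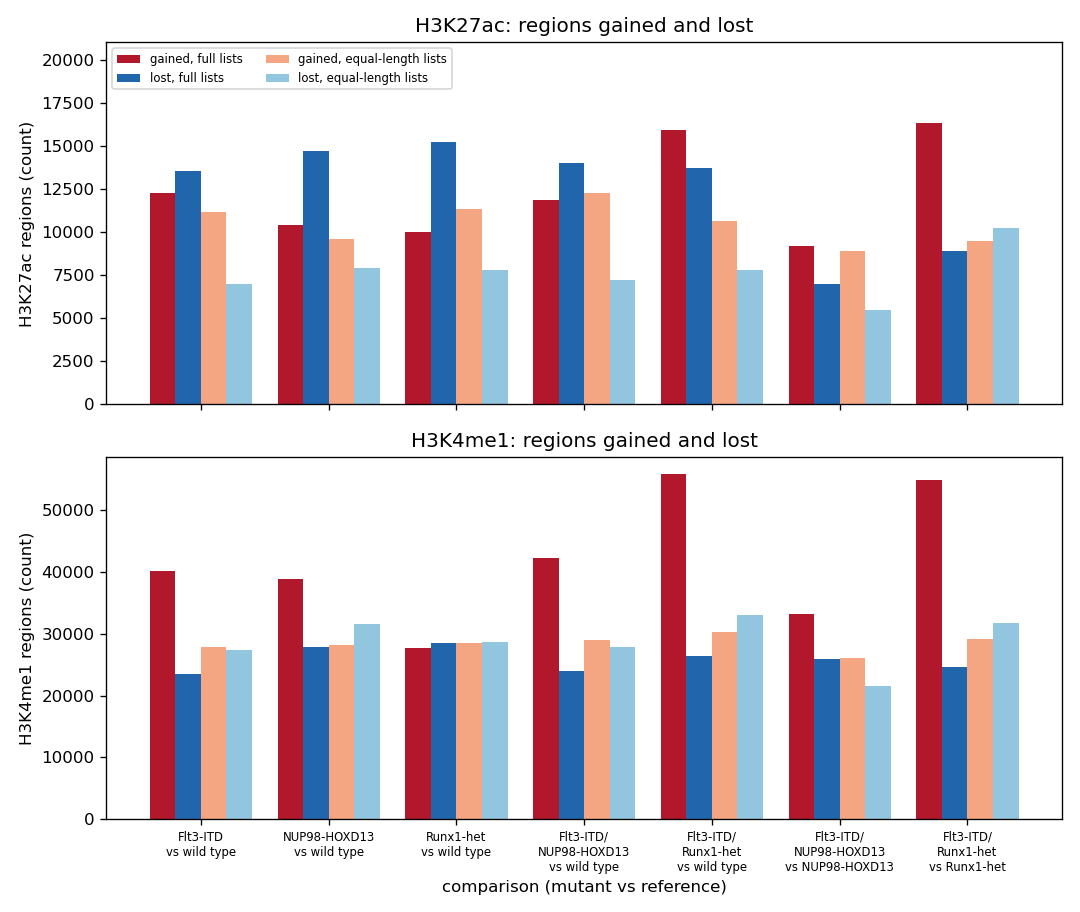
Regions gained and lost in the 7 comparisons, for H3K27ac (upper panel) and H3K4me1 (lower panel), as counts on the vertical axis. Dark bars are full lists and light bars lists shortened to equal length. For H3K27ac in Flt3-ITD against wild type, gained and lost regions number 12278 and 13540 in full lists and 11135 and 6986 in equal-length lists.

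NUP98-HOXD13 against wild type asks what the fusion does. H3K27ac was listed at HOXB and HOXC cluster genes, which encode homeodomain transcription factors, and at the gene of their partner PBX3. Promoter peaks at Hoxb6, Hoxb7, Hoxb8, Hoxc6, Hoxc8 and Pbx3 were in the 2 lists with the fusion and in none of the 4 others. The region over Hoxb8 and Hoxb7 (chromosome 11, 96276796 to 96287267) had a fold enrichment of 26.0 in NUP98-HOXD13 and 27.5 in Flt3-ITD/NUP98-HOXD13, the one at Hoxc4 (chromosome 15, 103013810 to 103020524) 25.2 and 23.0, and the one at Pbx3 (chromosome 2, 34360556 to 34372925) 21.6 and 34.6. HOX and cofactor promoters with a peak numbered 13 of 25 in both fusion lists against 6 or 7 in the others. Promoter peaks at Hoxa3, Hoxa7 and Hoxa9 were in all 6 lists, and that at Hoxa10 in Runx1-het and both fusion lists. The promoter peak at Hoxb4 was missing from Flt3-ITD/NUP98-HOXD13 alone. The gained share of the list as a whole, 11 gained and 9 lost regions, was at percentile 73.2. Meis1, the HOX cofactor gene, had 0 gained and 6 lost regions beside Pbx3 (3 and 0), Hoxc8 and Hoxb6 (2 and 0 each).

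The strongest gained regions of all were not at HOX genes. The region on chromosome 19 from 29731307 to 29746800, within 9930021J03Rik with Mlana as the nearest start site, had a fold enrichment of 46.7 in NUP98-HOXD13 and 59.5 in Flt3-ITD/NUP98-HOXD13, and a neighbouring region from 29749645 to 29757033 had 26.5 and 27. A region within Ascc3 (chromosome 10, 50633108 to 50643352), a helicase gene, had 29.8 and 43.6. These were outside the 4 lists without the fusion. Regions lost in NUP98-HOXD13 included those near Lrrc6 (12.9 in wild type), Rnf125 (10.3), Cpne2 (9.94), Coro2b (9.94) and Ap3b1 (9.52). Those near Rnf125, Coro2b and Ap3b1 were outside both fusion lists and inside the 4 others.

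Near HSC and multipotent progenitor genes, NUP98-HOXD13 had 28 H3K27ac regions gained and 60 lost, at percentile 6.08, inside the central 95%, and at 1.17 in equal-length lists, outside it. Mecom, a regulator of stem cell self-renewal, had 2 gained and 18 lost regions, Hlf, a stem cell transcription factor gene, 4 and 10, and Erg 6 and 4. For H3K4me1 the same list had 62 gained and 100 lost (percentile 0.150). A promoter peak at Mllt3, which encodes a stem cell maintenance factor, was missing from both fusion lists. STAT5 targets had 26 gained and 14 lost regions (percentile 98.7, 94.8 in equal-length lists and 93.9 without Ccnd3), with Ccnd3 at 9 and 3 and Ccnd1 at 3 and 0. The mast cell, basophil and eosinophil list had 13 and 5 (percentile 98.4, 91.9 in equal-length lists and 93.2 without Gata2), with Gata2 at 3 and 0. The other lists lay inside the central 95%, among them MAPK feedback genes with 33 gained and 29 lost (percentile 81.4), where Dusp5, a phosphatase gene acting on ERK, had 6 and 2 and the early response gene Egr3 6 and 1, and granulocyte genes with 11 and 13 (percentile 52.8), where the repressor gene Gfi1 had 0 and 6.

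Over the genome, NUP98-HOXD13 gained 10384 H3K27ac regions (37.2% of its regions, 36.6 to 37.7%) and lost 14691 (45.5% of the wild-type regions, 45.0 to 46.1%), a gained share of 41.4% that became 54.7% in equal-length lists. Promoters made up 17.6% (16.9 to 18.4%) of the gained regions, 3.58% of the lost and 44.0% of the shared ones. NUP98-HOXD13 gained 38875 H3K4me1 regions and lost 27829, and in equal-length lists 28158 and 31602, so the balance turned. The H3K4me1 list of this genotype held few peaks of high confidence: with −log10 q of at least 5 in every list, 2542 regions were gained and 18133 lost.

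**Figure D2:**
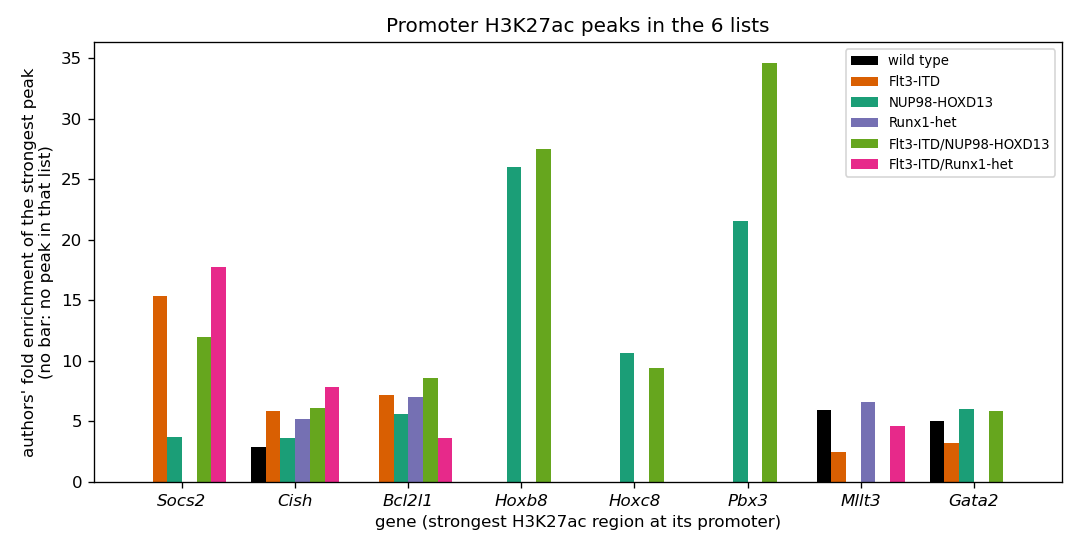
Authors' fold enrichment of the strongest H3K27ac region at the promoters of 8 genes (vertical axis) in the 6 lists (bars). A missing bar is a list without a peak there. Hoxb8, Hoxc8 and Pbx3 have bars in the 2 lists with NUP98-HOXD13 alone, Socs2 reaches 15.4, 12 and 17.8 in the 3 lists with Flt3-ITD, and the 8 genes were chosen after their values were seen.

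Runx1-het against wild type asks what goes with the Runx1 genotype. Its strongest gained H3K27ac regions were promoters on the Y chromosome: Ddx3y had a fold enrichment of 28.4 in Runx1-het and 19.2 in Flt3-ITD/Runx1-het, Uty 27 and 22.4, and Eif2s3y 11.7 and 11.5. No other list had these peaks, nor that at the Y-linked Kdm5d (6.70 and 5.49). The promoter of Xist, the RNA of the inactive X chromosome, had an H3K27ac peak in the other 4 lists (8.95 to 14.9) and in neither Runx1-het list. The comparison of Runx1-het with wild type is therefore also one of lists with a different sex-linked signal, which the comparison of Flt3-ITD/Runx1-het with Runx1-het is not.

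Away from the Y chromosome, the strongest gained regions lay near Mterf1a (13.1), a mitochondrial transcription terminator gene, and in Ccnd3 (11.5), and both were in all 5 mutant lists. Of the strongest lost regions, those near Gna11 (10.6 in wild type), Irs1 (9.28), Nmur1 (8.62) and Accsl (8.62) were missing from the Runx1-het list alone, and that near Gfod1 (9.28) was outside 4 mutant lists. T and NK cell genes had 1 region gained and 10 lost (percentile 2.27), with the transcription factor gene Tcf7 and the NK receptor gene Klrb1c at 0 and 3 each. This rose to 16.2 in equal-length lists and to 8.55 without Klrb1c. Megakaryocyte genes had 9 gained and 29 lost (percentile 3.35), 16 of the losses near Fli1, a transcription factor gene of that lineage. HSC and multipotent progenitor genes had 57 gained and 53 lost (percentile 91.5), with Cd34 at 7 and 1 and Mllt3 at 7 and 3, and STAT5 targets 18 and 16 (percentile 94.3).

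Over the genome, Runx1-het gained 10024 H3K27ac regions (37.0%, 36.5 to 37.6%) and lost 15207 (47.1%, 46.6 to 47.7%), and in equal-length lists gained 11358 and lost 7816. For H3K4me1, 27660 regions were gained and 28595 lost. Regions held by both Runx1-het lists and no other numbered 410 for H3K27ac, rank 11 among the 15 possible pairs of lists and below the 562 of a simulation that keeps the number of lists per region, and 1398 for H3K4me1, below a simulated 2017. Held by the 4 other lists alone were 200 H3K27ac regions (simulated 202) and 921 H3K4me1 regions (simulated 698). Runx1 itself had 4 of the 410 H3K27ac regions held by both Runx1-het lists and no other, the most of any gene, chosen after the values were seen. Runx1 is rich in regions, with 63 H3K27ac union regions. Of these, Runx1-het held 17, Flt3-ITD/Runx1-het 41 and wild type 20, so the 4 do not speak for a link to the genotype.

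Flt3-ITD/NUP98-HOXD13 against wild type shared its strongest gains with NUP98-HOXD13 alone. The regions near Mlana, in Ascc3, at Pbx3 and at Hoxb8 were among its 5 strongest gains, and its strongest losses included Robo4, a receptor gene of endothelium and stem cells (10.2 in wild type), which was missing from this list alone. HSC and multipotent progenitor genes had 27 regions gained and 53 lost (percentile 1.21, 5.35 without Mecom and 3.53 with start sites up to 100 kb away), with Mecom at 3 and 14, Hlf at 2 and 11 and Meis1 at 0 and 5. Erythroid genes had 2 gained and 10 lost (percentile 0.585, at most 1.30 whichever member was left out), with the carbonic anhydrase gene Car2 at 1 and 4 and Zfpm1, which encodes a GATA1 cofactor, at 1 and 2. Megakaryocyte genes had 9 and 24 (percentile 1.94), of which Fli1 gave 0 and 16, and without Fli1 the percentile was 56.3. T and NK cell genes had 2 and 10 (percentile 2.34, 18.1 in equal-length lists and 6.50 without Gata3). The negative control list of genes not expressed in blood leaned the same way, with 1 region gained and 6 lost. Its percentile was 3.75, and 2.74 against random lists matched also on fold enrichment, both inside the central range. Its gained share was 14.3%, against 16.7% for erythroid and for T and NK cell genes. A low gained share was therefore not particular to blood lineage genes in this comparison.

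On the gaining side of the same comparison, STAT5 targets had 31 regions gained and 10 lost (percentile 99.8, and 99.4 without Ccnd3), with Ccnd3 at 11 and 3, the survival gene Mcl1 at 3 and 1, and Socs2 and Bcl2l1 at 2 and 0 each. Interferon response genes had 34 and 18 (percentile 96.8), with the antiviral gene Rsad2 at 4 and 1 and the immunoproteasome gene Psmb8 at 3 and 0, and 92 and 29 for H3K4me1 (percentile 98.7). The positive control list of ubiquitous genes stood apart too, with 17 and 4 (percentile 99.3), 8 of the gains near Ywhaz. Without Ywhaz it was at 90.7, in equal-length lists at 84.8, and against random lists matched also on fold enrichment at 98.4. Over the genome 11881 H3K27ac regions were gained (39.4%, 38.8 to 40.0%) and 13980 lost (43.3%, 42.8 to 43.9%), and in equal-length lists 12256 and 7201. H3K4me1 regions gained numbered 42233 and lost 23911, against 29002 and 27909 in equal-length lists.

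Flt3-ITD/Runx1-het against wild type had the widest STAT5 target gain, 61 regions gained and 11 lost (percentile 99.9), with Ccnd3 at 12 and 4, Socs2 and Socs1 at 7 and 0 each and Socs3, a further cytokine feedback inhibitor, at 6 and 0. Promoter peaks at Socs3 and at Il2ra, the interleukin 2 receptor alpha chain gene, were in this list alone. The mast cell, basophil and eosinophil list had 27 gained and 4 lost (percentile 99.4, and 96.8 in equal-length lists), with Kit at 8 and 1, Il4 at 6 and 0, the histamine synthesis gene Hdc at 6 and 1 and Gata2 at 5 and 1. The promoter peak of Gata2 in wild type was missing from the Flt3-ITD/Runx1-het list. The granulocyte list had 24 and 8 (percentile 92.3), with the myeloperoxidase gene Mpo at 7 and 1 and the cathepsin gene Ctsg at 3 and 0. B lymphoid genes had 14 and 23 (percentile 3.53), with the genome organizer gene Satb1 at 0 and 7. The strongest gains off the Y chromosome were Socs2 (17.8), Kcnab2 (16.5) and Arl2bp (16), and the strongest losses included regions near Dtnbp1 (8.95 in wild type), Pkd2l2 (8.95) and Fam198b (8.62), each missing from this list alone.

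This double mutant gained 15931 H3K27ac regions (46.2%, 45.7 to 46.7%) and lost 13711 (42.5%, 42.0 to 43.0%), and in equal-length lists 10620 and 7818. In H3K4me1, 55850 regions were gained and 26440 lost, and in equal-length lists 30270 and 33030, where the balance turned. For H3K4me1 the STAT5 targets had 177 gained and 26 lost (above all 10000 random lists), T and NK cell genes 62 and 9 (percentile 99.2), and HOX and cofactor genes 22 and 24 (percentile 0.465).

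Flt3-ITD/NUP98-HOXD13 against NUP98-HOXD13 asks what Flt3-ITD adds to the fusion. Interferon response genes had 23 H3K27ac regions gained and 7 lost (percentile 98.1), with Rsad2 and Psmb8 at 3 and 0 each and Rtp4 and Oas3, both induced by interferon, at 2 and 0 each. The strongest gained region lay at the promoter of Tgtp1, an interferon-induced GTPase gene outside the list (chromosome 11, 48993199 to 48995431, fold enrichment 12.6), and it was missing from the NUP98-HOXD13 list alone. The interferon percentile was 96.9 in equal-length lists, 95.8 against random lists matched also on fold enrichment and 96.3 without Rsad2, so this call lay at the edge. Interferon promoters with a peak numbered 41 of 43 in both lists. STAT5 targets had 24 gained and 15 lost (percentile 60.4), with Ccnd3 at 6 and 4 and Pim1 at 4 and 1, so they did not stand apart here.

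Other members that changed in this comparison were the receptor gene Flt3, at 6 gained and 0 lost regions in the dendritic cell list (24 and 14, percentile 61.9), and Mecom, at 7 and 2 in the HSC and multipotent progenitor list (30 and 24, percentile 31.0). MAPK feedback genes had 14 and 22 (percentile 3.0), with Fos at 1 and 4 and Dusp5 at 2 and 4. Gained regions near Gm4951 (10.6), the axon guidance receptor gene Plxnc1 (7.57), the cytokine gene Il13 (7.57) and Rnf122 (7.49) followed Tgtp1. Lost regions near Egfl7 (7.79 in NUP98-HOXD13), Litaf (7.51), Rassf3 (7.32), Gm45844 (7.16) and Agpat3 (6.63) were the strongest. This pair had the most alike lists of each mark, with a Jaccard index of 0.564 for H3K27ac and 0.428 for H3K4me1, where the wild-type H3K27ac list had 0.385 to 0.420 with the others. For H3K27ac these were also the only lists pooled from 4 samples. Gained H3K27ac regions numbered 9213 (30.6%, 30.0 to 31.1%) and lost ones 7005 (25.1%, 24.6 to 25.6%), and in equal-length lists 8885 and 5467. H3K4me1 regions gained numbered 33218 and lost 25942, against 26051 and 21514.

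Flt3-ITD/Runx1-het against Runx1-het asks the same in the Runx1-het background. STAT5 targets stood apart on the gaining side and stem cell genes on the losing side. The STAT5 targets had 56 regions gained and 8 lost (percentile 99.1, and 97.4 without Socs2), with Socs1 at 8 and 1, Socs2 at 7 and 0, Ccnd3 at 7 and 2 and Pim1 at 6 and 0. HSC and multipotent progenitor genes had 46 and 52 where most lists gained far more than they lost (percentile 0.540, at most 1.85 whichever member was left out), with Mecom at 5 and 11, Hlf at 1 and 8 and Mllt3 at 2 and 7. HOX and cofactor genes had 3 and 6 (percentile 1.54), of which Meis1 gave 1 and 4, and without Meis1 the percentile was 16.7, and it was 3.39 against random lists matched also on fold enrichment. Meis1 is in both of these lists.

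Inside the central 95% of random lists, megakaryocyte genes had 36 regions gained and 11 lost, with the thrombin receptor gene F2r at 11 and 1 and Fli1 at 10 and 2. Granulocyte genes had 27 and 6, with Mpo at 7 and 0. MAPK feedback genes had 29 and 20, with Dusp5 at 13 and 0. Monocyte and macrophage genes had 26 and 18, with Irf8, a transcription factor gene of monocytes and dendritic cells, at 6 and 0. The strongest gained regions were Socs2 (17.8), Stub1 (16.7), Fbxw4 (12.1), Grk5 (12.1) and Sec14l1 (11.9), of which all but Socs2 were missing from the Runx1-het list alone. The strongest lost ones lay near Yeats4 (12.7 in Runx1-het), Spry2 (9.80), Cdca7l (8.95), Herpud2 (8.13) and Tas2r143 (8.01).

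Gained H3K27ac regions in this comparison numbered 16301 (47.3%, 46.8 to 47.8%) and lost ones 8898 (32.9%, 32.3 to 33.4%), a gained share of 64.7%. In equal-length lists 9486 were gained and 10226 lost, a gained share of 48.1%, so the balance turned with list length. There were 54978 H3K4me1 regions gained and 24633 lost, and 29144 and 31754 in equal-length lists. For H3K4me1 the STAT5 targets had 163 gained and 23 lost (percentile 99.9), erythroid genes 57 and 8 (percentile 98.3), T and NK cell genes 63 and 8 (percentile 99.1), HSC and multipotent progenitor genes 105 and 93 (percentile 1.18) and HOX and cofactor genes 20 and 22 (percentile 0.470).

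**Figure D3:**
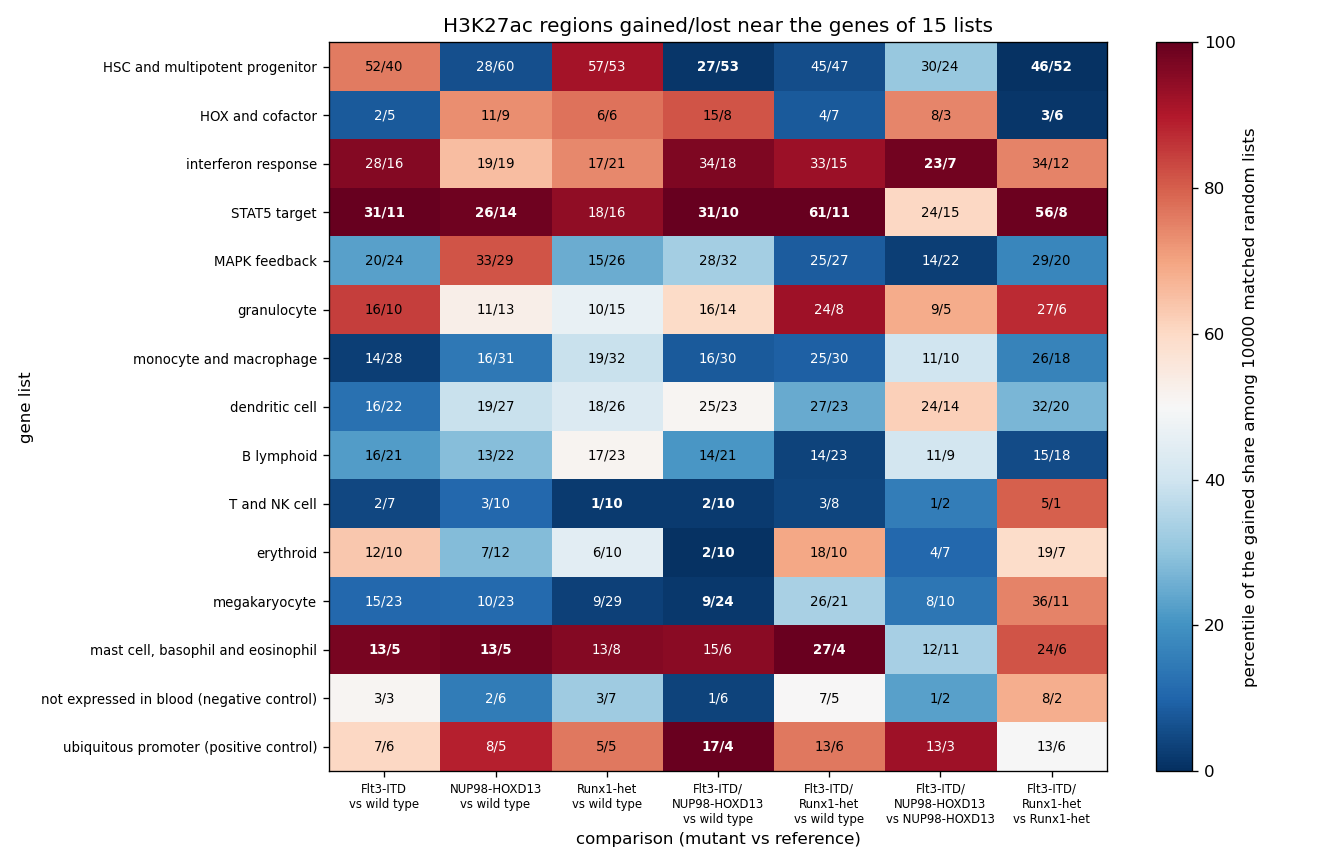
H3K27ac regions gained and lost (numbers in the cells) near the genes of 15 lists (vertical axis) in 7 comparisons (horizontal axis). Colour is the percentile of the gained share among 10000 matched random lists, and bold marks values outside the central 95%. STAT5 targets are in bold in 5 of the 7 columns, with a percentile of 60.4 in Flt3-ITD/NUP98-HOXD13 against NUP98-HOXD13.

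Of the 105 H3K27ac percentiles, 15 lists in 7 comparisons, 10 lay above and 7 below the central 95%, where 5.25 would fall outside by chance if the percentiles were independent. For H3K4me1 9 lay above and 4 below. Comparisons against wild type share the wild-type list and the lists share members (Irf8, Kit, Gata2, Meis1, Hoxb5 and Id2, among others, are each in 2), so the percentiles are not independent. The mast cell, basophil and eosinophil list leaned to gains in all 5 comparisons against wild type. Matched also on fold enrichment, its percentiles there were 97.455 to 99.5. They were 44.0 against NUP98-HOXD13 and 81.3 against Runx1-het, so the high values cannot be credited to single genotypes. In equal-length lists 4 H3K27ac percentiles lay above, all of them STAT5 targets in comparisons of a Flt3-ITD list. Others lay below, among them HSC and multipotent progenitor genes in NUP98-HOXD13 and HOX and cofactor genes in Flt3-ITD/Runx1-het, both against wild type.

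Regions that followed a genotype factor across all its lists were counted next, a count added after the data were seen. The 2 lists with NUP98-HOXD13, and no other, held 993 H3K27ac regions, the most of the 15 possible pairs (next highest 952) and above the 419 regions of a simulation that keeps the number of lists per region. Equal-length lists gave 1047. Cldn14, Lin28b and Tmem47 had 6 such regions each. The 2 fusion lists were also the only H3K27ac lists pooled from 4 samples, the others from 3. For this count the fusion and the number of pooled samples cannot be told apart. H3K27ac regions held by the 4 lists without the fusion and by neither fusion list numbered 314, about the simulated 303, and the strongest lay at the promoter of Nkx2-3, a homeobox gene (chromosome 19, 43607245 to 43614561, 7.27 to 10.0), and near Clec2g, Cage1, Fnbp1l and Umodl1. The 3 lists with Flt3-ITD alone held 502 H3K27ac regions against a simulated 330, the second most of the 20 sets of 3 lists. The most, 696 against a simulated 241, were in NUP98-HOXD13, Flt3-ITD/NUP98-HOXD13 and Flt3-ITD/Runx1-het. That set follows no genotype factor, so such an excess was not particular to Flt3-ITD. The strongest of the 502 lay near Ect2l, Tppp3, Zfp516, Crisp1 and Gcn1l1 (4.96 to 5.48 in the list where each was weakest). The 3 lists without Flt3-ITD alone held 72 regions, below a simulated 142. For H3K4me1 the 3 lists with Flt3-ITD alone held 1555 regions, below a simulated 1943, and the 3 without it 246, below a simulated 336. The 2 fusion lists held 3225 H3K4me1 regions, above a simulated 2131 and second to another pair (3562) in full lists, and in equal-length lists 2370, the most of any pair (next 2310). Each of the 15 gene lists had at most 9 of the H3K27ac regions that followed a factor, too few for a ranking among random lists.

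Whether Flt3-ITD changed the same regions in each background was tested on regions that could change in both. Of the H3K27ac regions lost in a pair of backgrounds, 483 to 787 were lost in both, 5.73 to 6.16 times the number under independence. Both simulations without a genotype effect gave 3.88 to 5.05 times. The counts went the other way. In each pair, fewer regions were lost in both than in the simulation that keeps the number of lists per region. The higher ratio therefore does not show that more losses were shared than without a genotype effect. For gained regions the observed overlap was 0.603 to 0.688 times independence, between the simulation that keeps the number of lists per region (0.471 to 0.557) and the one with a probability per region (1.20 to 1.24), so the comparison does not decide for H3K27ac gains. For H3K4me1 gains the ratio lay between the simulations with wild type and NUP98-HOXD13 as backgrounds (0.795 against 0.663 and 1.25) and below both for the other pairs (0.667 against 0.700 and 1.22, and 0.520 against 0.636 and 1.21). In equal-length lists 0.667 became 0.643, between the simulations (0.600 and 1.28), and 0.520 became 0.555, still below both. For H3K4me1 losses the observed ratio was 2.42 to 2.94, above both simulations for wild type with NUP98-HOXD13 as backgrounds (2.94 against 2.33 and 2.63) and below both for the other pairs. In equal-length lists these other pairs lay between the simulated means (1.96 against 1.89 and 2.19, and 1.95 against 1.93 and 2.26).

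Regions held by a double mutant and by neither single mutant nor wild type numbered 5714 for H3K27ac in Flt3-ITD/NUP98-HOXD13 (18.9% of its regions, 18.5 to 19.4%) and 10629 in Flt3-ITD/Runx1-het (30.8%, 30.3 to 31.3%). The same sets of 4 lists held 11222 and 10937 regions in wild type alone. For Flt3-ITD/Runx1-het the count lay above both simulations (6622 and 9974), and for Flt3-ITD/NUP98-HOXD13 between them (4736 and 7381). In equal-length lists the Flt3-ITD/Runx1-het count was 5774. It was not set beside a simulation of equal-length lists, so whether the excess remains there was not tested. Regions missing from the double mutant alone numbered 629 in Flt3-ITD/NUP98-HOXD13, below both simulations (1312 and 1278). In Flt3-ITD/Runx1-het they numbered 832, against a simulated 964 and 848. Regions of H3K27ac in all 5 mutant lists and not in wild type numbered 1128, the most of the 6 counts of regions missing from a single list (250 to 1087 for the others), and 1358 in equal-length lists. The wild-type list had the narrowest peaks (median 389 bp) and the smallest share with −log10 q of at least 5 (37.7%). Gains common to the mutants therefore cannot be told apart here from peaks missed in wild type.

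How often changed H3K27ac lay on H3K4me1 was measured against the reference list. In the 7 comparisons 31.6 to 51.8% of gained regions overlapped an H3K4me1 peak of the reference list, against 64.5 to 74.1% of the shared regions. Lost regions overlapped one in 26.9 to 54.5%. Overlap was counted from 1 bp, and regions were not matched on width or strength. Gained regions ranked lower within the mutant list (median percentiles 22.2 to 28.5) than shared ones (65.3 to 72.8). How far this accounts for the gap was not tested. Promoters made up 7.04 to 17.6% of gained, 2.98 to 8.07% of lost and 41.0 to 44.0% of shared H3K27ac regions.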

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

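Of the tests in this part, the one against random lists matched on fold enrichment was fixed before its result was seen, and the others were chosen after the values they use had been seen.

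Near HSC and multipotent progenitor genes, Flt3-ITD gained more H3K27ac regions than it lost in 2 backgrounds and fewer in Runx1-het. The gained share of changed regions was 56.5% against wild type, 55.6% against NUP98-HOXD13 and 46.9% against Runx1-het, and the difference was not tested. The direction of the raw Runx1-het counts rested on single genes. Of 46 regions gained and 52 lost, 45 and 44 were left without Hlf, 41 and 41 without Mecom and 46 and 46 without Angpt1. In all, 10 members gained more than they lost against 8 with the reverse. The low share beside random lists did not rest on 1 gene: its percentile was 0.540, at most 1.85 whichever member was left out. Random lists matched also on fold enrichment had median gained shares of 51.0% against wild type, 57.9% against NUP98-HOXD13 and 69.9% against Runx1-het. Over all H3K27ac regions the gained share was 47.6% against wild type, 56.8% against NUP98-HOXD13 and 64.7% against Runx1-het. This difference was not tested either, and equal-length lists turned 47.6 into 61.4% and 64.7 into 48.1%.

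Promoter H3K27ac at the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d was in both Runx1-het lists and in no other. In 6 of 6 H3K27ac lists either Y-linked promoter peaks or the Xist promoter peak were present but not both, a result consistent with the sex of the animals as the source of the signal. The Runx1 genotype as the source was looked at through the lists without it: 0 of them held a Y-linked promoter peak, but all 4 held the Xist peak. Peaks on the Y chromosome need a Y chromosome, and Runx1 lies on chromosome 16. The peaks at 4 of 4 Y-linked genes in both Runx1-het lists therefore argue against the Runx1 genotype alone as their source. For all other differences the Runx1 genotype and sex cannot be told apart here. The labels do not give the sex, and pooled lists do not show whether single animals differed. Any difference between a Runx1-het list and wild type may therefore carry an effect of sex, on autosomes too, which was not tested.

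The H3K27ac region in the first part of Vav1 (chromosome 17, 57288366 to 57292406) had a fold enrichment of 5.41 in wild type, 4.21 in Flt3-ITD, 13.7 in NUP98-HOXD13, 16.1 in Runx1-het, 26.3 in Flt3-ITD/NUP98-HOXD13 and 15.3 in Flt3-ITD/Runx1-het. The source labels name Vav for the Runx1-het lines, and Vav1 sequences drive the fusion in the NUP98-HOXD13 mouse as background knowledge. In equal-length lists the strongest Vav1 peak of a carrier ranked above that of a non-carrier in 16 of 16 pairs over both marks. For H3K27ac this restates what drew attention to the gene. The strongest H3K4me1 region of NUP98-HOXD13 and of Runx1-het lay elsewhere, at the start site (16.3 and 16.7). There wild type had no peak and Flt3-ITD had 7.19. The H3K4me1 region that overlaps the H3K27ac one had 10.9 to 14.1 in carrier lists, against 5.91 in wild type and 5.77 in Flt3-ITD. The count therefore does not decide for or against extra copies of Vav1 sequence in transgenes. The 6 other Vav1 H3K27ac regions were also held more often by carriers, by 33.3 percentage points, although Flt3-ITD held as many (3) as both Runx1-het lists. This is the direction that regulation of Vav1 as a whole would give. All 6 lay between 57274647 and 57287506, however, around the start of a gene that ends at 57328031. They therefore cannot tell regulation of the whole gene from extra copies of its first part. Both explanations stay open, because the transgene sequences were not analysed here.

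The STAT5 target list stood apart on the gaining side in 4 comparisons of a Flt3-ITD list. Against random lists matched also on fold enrichment the lowest of the 4 percentiles was 99.2. In Flt3-ITD/NUP98-HOXD13 against wild type the positive control list also stayed outside the central 95% under this matching (98.4). There the test cannot decide on highly acetylated genes missed by a shallower reference list. Elsewhere the positive control lay inside (58.4 in Flt3-ITD and 82.6 in Flt3-ITD/Runx1-het against wild type, 64.1 against Runx1-het). In those comparisons the STAT5 percentiles argue against such genes as the whole cause. The test without 1 member was first set over all 4 comparisons together and was divided by reference after those values were seen. Against wild type no single member carried the result, with a lowest percentile of 98.45 (without Ccnd3), whereas against Runx1-het it was 97.4 without Socs2, just inside the central 95%, with 49 regions gained and 8 lost where the full list had 56 and 8, so the share hardly moved and the values do not point to a single gene. Flt3-ITD as a cause acting in each background is not settled, because the percentile was 60.4 against NUP98-HOXD13, NUP98-HOXD13 without Flt3-ITD was at 98.7 against wild type, and sampling of animals was not tested.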

How the results depend on the processing

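Alternatives that match random lists also on fold enrichment, leave out a member, or count regions by genotype factor were chosen after the data were seen, and the others were planned. No paired analysis was possible because only the pooled list of each group was used, and for the same reason no replicate was left out in turn. The motif alternative was not run because the genome sequence was not at hand. Read depth is unknown, so how far it limits the counts could not be measured. Comparisons below are against wild type unless another reference is named, and the cause of a change was not tested unless stated. With autosomes only, all 36 counts stayed within 1.5 times, which says nothing about sex, since the X chromosome held at most 1.55% of H3K27ac peaks. Among single gene-list percentiles, equal-length lists left 120 on their side of the central range, took 9 into it and 2 out of it, start sites within 100 kb left 126, took 5 in and 4 out, and matching also on fold enrichment left 99, took 3 in and 3 out. Those taken out were, in equal-length lists, HSC and multipotent progenitor genes in NUP98-HOXD13 (1.17) and HOX and cofactor genes in Flt3-ITD/Runx1-het (2.495). With start sites within 100 kb they were HOX and cofactor genes in Runx1-het (97.6), interferon response genes in Flt3-ITD/NUP98-HOXD13 (98.6), MAPK feedback genes in Flt3-ITD/NUP98-HOXD13 against NUP98-HOXD13 (1.55) and monocyte and macrophage genes in Flt3-ITD (2.32). Matching on fold enrichment took out the last 2 (2.31 and 2.19) and the mast cell, basophil and eosinophil list in Runx1-het (97.98). Leaving out the member that moved a percentile most left 6 outside and brought 10 inside, beside the megakaryocyte list named below.

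With only peaks of −log10 q of at least 5 in every list, H3K27ac regions gained numbered 7560 in Flt3-ITD, 3920 in NUP98-HOXD13, 7378 in Flt3-ITD/NUP98-HOXD13, 5947 in Flt3-ITD/Runx1-het, 5386 in Flt3-ITD/NUP98-HOXD13 against NUP98-HOXD13 and 3806 in Flt3-ITD/Runx1-het against Runx1-het. H3K27ac regions lost numbered 1420 in Flt3-ITD, 2928 in NUP98-HOXD13, 1706 in Runx1-het, 1905 in Flt3-ITD/NUP98-HOXD13, 2251 in Flt3-ITD/Runx1-het, 905 in Flt3-ITD/NUP98-HOXD13 against NUP98-HOXD13 and 5539 in Flt3-ITD/Runx1-het against Runx1-het. A double mutant and none of its 3 reference lists held 2674 H3K27ac regions in Flt3-ITD/NUP98-HOXD13 and 1970 in Flt3-ITD/Runx1-het. Missing from a double mutant alone were 146 H3K27ac regions in Flt3-ITD/NUP98-HOXD13. H3K4me1 regions gained numbered 10619 in Flt3-ITD, 2542 in NUP98-HOXD13, 10931 in Runx1-het, 8845 in Flt3-ITD/NUP98-HOXD13, 10743 in Flt3-ITD/Runx1-het, 13682 in Flt3-ITD/NUP98-HOXD13 against NUP98-HOXD13 and 10617 in Flt3-ITD/Runx1-het against Runx1-het. H3K4me1 regions lost numbered 11580 in Flt3-ITD, 18133 in NUP98-HOXD13, 11641 in Runx1-het, 12807 in Flt3-ITD/NUP98-HOXD13, 14649 in Flt3-ITD/Runx1-het, 2053 in Flt3-ITD/NUP98-HOXD13 against NUP98-HOXD13 and 13813 in Flt3-ITD/Runx1-het against Runx1-het. A double mutant and none of its 3 reference lists held 5309 H3K4me1 regions in Flt3-ITD/NUP98-HOXD13 and 6874 in Flt3-ITD/Runx1-het. A double mutant alone lacked 394 H3K4me1 regions in Flt3-ITD/NUP98-HOXD13.

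In equal-length lists, H3K27ac regions gained numbered 10620 in Flt3-ITD/Runx1-het and 9486 in Flt3-ITD/Runx1-het against Runx1-het. H3K27ac regions lost numbered 6986 in Flt3-ITD, 7938 in NUP98-HOXD13, 7816 in Runx1-het, 7201 in Flt3-ITD/NUP98-HOXD13 and 7818 in Flt3-ITD/Runx1-het. A double mutant and none of its 3 reference lists held 5774 H3K27ac regions in Flt3-ITD/Runx1-het. H3K4me1 regions gained numbered 30270 in Flt3-ITD/Runx1-het and 29144 in Flt3-ITD/Runx1-het against Runx1-het. A double mutant and none of its 3 reference lists held 18244 H3K4me1 regions in Flt3-ITD/Runx1-het. The lists with a genotype factor and no others held 747 H3K4me1 regions for Flt3-ITD. The lists without a genotype factor and no others held 420 H3K4me1 regions for Flt3-ITD.

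With the strongest peaks of 1 list set against the full other list, H3K27ac regions gained numbered 9160 in Flt3-ITD/Runx1-het and 9409 in Flt3-ITD/Runx1-het against Runx1-het. H3K27ac regions lost numbered 6530 in Flt3-ITD, 7458 in NUP98-HOXD13, 7750 in Runx1-het, 6932 in Flt3-ITD/NUP98-HOXD13 and 6776 in Flt3-ITD/Runx1-het. A double mutant and none of its 3 reference lists held 5118 H3K27ac regions in Flt3-ITD/Runx1-het. Missing from a double mutant alone were 374 H3K27ac regions in Flt3-ITD/NUP98-HOXD13. The lists with a genotype factor and no others held 286 H3K27ac regions for Flt3-ITD and 245 for Runx1-het. The lists without a genotype factor and no others held 42 H3K27ac regions for Flt3-ITD, 191 for NUP98-HOXD13 and 112 for Runx1-het. H3K4me1 regions gained numbered 29356 in Flt3-ITD/Runx1-het, 21025 in Flt3-ITD/NUP98-HOXD13 against NUP98-HOXD13 and 28430 in Flt3-ITD/Runx1-het against Runx1-het. H3K4me1 regions lost numbered 16427 in Flt3-ITD/NUP98-HOXD13 against NUP98-HOXD13. A double mutant and none of its 3 reference lists held 10642 H3K4me1 regions in Flt3-ITD/NUP98-HOXD13 and 16008 in Flt3-ITD/Runx1-het. A double mutant alone lacked 1343 H3K4me1 regions in Flt3-ITD/NUP98-HOXD13. The lists with a genotype factor and no others held 526 H3K4me1 regions for Flt3-ITD, 1534 for NUP98-HOXD13 and 731 for Runx1-het. The lists without a genotype factor and no others held 366 H3K4me1 regions for NUP98-HOXD13 and 504 for Runx1-het.

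With at least 0.5 of the union region covered, H3K27ac regions gained numbered 18369 in Flt3-ITD/NUP98-HOXD13. Missing from a double mutant alone were 204 H3K27ac regions in Flt3-ITD/NUP98-HOXD13. A double mutant alone lacked 1025 H3K4me1 regions in Flt3-ITD/NUP98-HOXD13.

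With the peaks of a pair of lists compared directly, missing from a double mutant alone were 982 H3K27ac regions in Flt3-ITD/NUP98-HOXD13 and 1824 in Flt3-ITD/Runx1-het. A double mutant alone lacked 7239 H3K4me1 regions in Flt3-ITD/Runx1-het.

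In equal-length lists the percentage of gained H3K27ac regions on reference H3K4me1 was 43.7 in Flt3-ITD, 37.0 in NUP98-HOXD13, 41.0 in Runx1-het, 40.6 in Flt3-ITD/NUP98-HOXD13, 36.6 in Flt3-ITD/Runx1-het, 47.4 in Flt3-ITD/NUP98-HOXD13 against NUP98-HOXD13 and 35.9 in Flt3-ITD/Runx1-het against Runx1-het. The overlap of gains against wild type moved to the other side of independence in 6 pairs, which shows no change in itself, since both members of a pair share the wild-type list and the simulations without a genotype effect gave other values than independence. For H3K27ac the ratio was 1.14 for Flt3-ITD with Flt3-ITD/Runx1-het (0.876 in full lists), 1.25 for NUP98-HOXD13 with Flt3-ITD/Runx1-het (0.982 in full lists) and 1.13 for Flt3-ITD/NUP98-HOXD13 with Flt3-ITD/Runx1-het (0.968 in full lists). For H3K4me1 it was 0.846 for NUP98-HOXD13 with Runx1-het (1.07 in full lists), 1.03 for NUP98-HOXD13 with Flt3-ITD/Runx1-het (0.947 in full lists) and 0.966 for Runx1-het with Flt3-ITD/NUP98-HOXD13 (1.19 in full lists). The number of H3K27ac list percentiles above the central range was 4 in equal-length lists. The megakaryocyte percentile in Flt3-ITD/NUP98-HOXD13 against wild type went to 56.3 without Fli1, an alternative chosen after the data were seen, because Fli1 held 16 of the 24 lost regions.

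With promoters taken to 2 kb, the percentage of gained H3K27ac regions at promoters was 14.9 in Flt3-ITD, 21.6 in NUP98-HOXD13, 11.8 in Runx1-het, 20.5 in Flt3-ITD/NUP98-HOXD13, 17.0 in Flt3-ITD/Runx1-het, 11.99 in Flt3-ITD/NUP98-HOXD13 against NUP98-HOXD13 and 16.3 in Flt3-ITD/Runx1-het against Runx1-het. For H3K4me1 the same percentage was 16.004 in Flt3-ITD, 19.1 in NUP98-HOXD13, 14.8 in Runx1-het, 16.8 in Flt3-ITD/NUP98-HOXD13, 16.2 in Flt3-ITD/Runx1-het, 14.7 in Flt3-ITD/NUP98-HOXD13 against NUP98-HOXD13 and 16.2 in Flt3-ITD/Runx1-het against Runx1-het. These rose because a wider promoter takes in more regions.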

Other observations

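The 15 gene lists also differed in which promoters carried H3K27ac, and the genes of this paragraph were chosen after their values were seen. Interferon response promoters with a peak numbered 34 of 43 in wild type, 37 in Flt3-ITD, 41 in NUP98-HOXD13, 35 in Runx1-het, 41 in Flt3-ITD/NUP98-HOXD13 and 38 in Flt3-ITD/Runx1-het. The promoters of Eif2ak2, which encodes the double-stranded RNA sensor PKR (fold enrichment 5.42 to 13.8), and Ifit3 (3.88 to 10.3) had a peak in all 5 mutant lists and not in wild type, and Oas1a, an RNA sensor gene, in Flt3-ITD/NUP98-HOXD13 alone (4.37). MAPK feedback promoters numbered 16 of 17 in NUP98-HOXD13 and 14 in Flt3-ITD/NUP98-HOXD13 against 11 or 12 in the other lists, with Spry4, a receptor kinase inhibitor gene (4.63 and 3.65), and Egr3 (4.50 and 4.44) in the 2 fusion lists alone. Wild type had the fewest protein-coding promoters with a peak, 8598, so part of such differences runs along with the lists as a whole. The 2 fusion lists were also the only H3K27ac lists pooled from 4 samples.

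Single stem cell and granulocyte promoters differed as well, and these genes too were chosen after their values were seen. HSC and multipotent progenitor promoters with a peak numbered 13 of 20 in wild type, Flt3-ITD and NUP98-HOXD13. They numbered 10 in Runx1-het and 14 in both double mutants, so most of these lists were nearly alike. Granulocyte promoters with a peak numbered 4 of 18 in wild type and 5 to 9 in the mutants. The promoter of Prdm16, a stem cell regulator gene, had a peak in wild type (4.34) and Flt3-ITD (7.48) alone. The promoters of Ctnnal1, Ly6a, Fgd5 and Hoxb5 went the other way, without a peak in wild type and with a peak in mutant lists. Among granulocyte genes, Ctsg had a promoter peak in Flt3-ITD (4.90), NUP98-HOXD13 (2.95), Flt3-ITD/NUP98-HOXD13 (3.71) and Flt3-ITD/Runx1-het (7.10), and Cebpe, a transcription factor gene of late granulocyte differentiation, in Flt3-ITD/NUP98-HOXD13 (4.18) and Flt3-ITD/Runx1-het (5.13). The promoter of Cebpd, also a granulocyte list gene, had a peak in the lists without the fusion and in neither fusion list. Among STAT5 targets, the promoter of the survival gene Bcl2l1 had a peak in all 5 mutant lists (3.67 to 8.56) and not in wild type. The region at the promoter of Cish, the feedback inhibitor gene most directly induced by STAT5, was in all 6 lists, at 2.87 in wild type and 3.67 to 7.81 in the mutants, and the wild-type peak lay farther than 1 kb from the start site.

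Some of the strongest H3K27ac regions held by the 2 fusion lists alone were wide and partly under H3K4me1 in those lists. The region near Mlana was under H3K4me1 over 25.4% of its length in NUP98-HOXD13, 50.2% in Flt3-ITD/NUP98-HOXD13 and 1.21% in wild type, and the one in Ascc3 over 13.2 and 48.5%, with none in the other 4 lists. A region within Adk, the adenosine kinase gene (chromosome 14, 21143264 to 21157202), farther than 50 kb from its start site, had a fold enrichment of 25.1 and 36.5 and was under H3K4me1 over 35.9 and 69.1%. The region at Hoxb8 was under H3K4me1 over 0.0764% in NUP98-HOXD13 and 2.04% in Flt3-ITD/Runx1-het, which lacks the fusion, and had none in Flt3-ITD/NUP98-HOXD13. The region near Lin28b had no H3K4me1 in any list, and the one near Igip had it in all 6, over 9.59 to 64.3%, with 30.6% in wild type.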
